A study of Mus musculus with 6 samples.

How the data were processed

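The series holds Affymetrix Mouse MOE430 2.0 arrays of E13.5 ventral forebrain from Olig2-/- and Olig2+/+ embryos, with 6 ug of total RNA labelled per array and RNA of 3 brains pooled per replicate, per the labels' protocols and the series design text. The 6 arrays analysed here are knockout replicates 2, 4 and 5 and wild-type replicates 1, 4 and 5. The genotype and the replicate number were taken from the sample titles.

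The values used are log2 expression values per probe set as deposited by the authors. Per the series design text, images were processed with GCOS and MAS 5.0, and probe signals were quantile-normalized, summarised and turned to the log2 scale with GCRMA. The submitters' processing notes name the same tools, and their versions are not given in the sources used here. The design text also describes a filter on detected probe sets, but the table holds 45101 probe sets, 64 of them AFFX controls, and shows no such filter. GCRMA subtracts background by probe sequence, which leaves a floor: about 33% of values on each array lie within 0.03 of it. Differences between genes near that floor are compressed, and differences between bright genes can be compressed by saturation. Quantile normalization gives the arrays nearly equal distributions, so a change in total RNA per cell cannot be seen.

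Probe sets were named from the platform's annotation. Of 45037 non-control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. Of those with 1 symbol, 34741 were matched by gene ID to a RefSeq table of assembly GRCm38, which updated 0 symbols and was also used to find the neighbours of Olig2. Probe sets with several symbols or none were tested and counted but not named. A probe set was kept if it was above its array's own median over non-control probe sets on at least 3 of the 6 arrays, counted without regard to genotype, which kept 22565. A gene was represented by its kept probe set of highest mean over the 6 arrays, which gave 10630 genes, and disagreeing probe sets of a named gene are stated.

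The genotypes were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without a fold limit), with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. Replicate numbers 4 and 5 occur in both genotypes, but the labels do not say that a number marks a shared litter or day, so the main comparison has no block. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 with adjustment over the 35 lists of at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. For each list, members were also counted after adjustment over the list alone. That adjustment was made separately in each of the 38 lists, some of which share genes, without correction across lists. Single values were compared with exact permutation tests, for which 0.1 is the smallest p that 3 against 3 can give.

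The test, the filter, the 38 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Olig2 and Olig1, then the 10 genes with the largest change per direction among those past the threshold whose groups did not overlap. Where fewer than 10 passed, it named the 10 of lowest p per direction without overlap, as not passed. For each list described it named up to 4 members, those of lowest p where none passed. Alternatives were other filters (none, log2 above 4 on 3 arrays, mean above the median of means), repeated quantile normalization, median centring, a trended robust variance, array weights, a replicate block, the mean of a gene's probe sets, a fold limit of 1 on the log2 scale, the other list tests, and each array left out in turn. Added after seeing the data were a block for knockout replicate 2 and wild-type replicate 4, leaving both out, and the cell cycle level as a covariate.

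The limma step was tested on simulated data with the means of the 22565 probe sets and spreads drawn at random from limma's fitted prior. Among them, 200 of mean above 5 were changed by known amounts. Limma called 10% of those changed by 0.5 on the log2 scale, 66% at 1, 88% at 2 and 96% at 3, and 4 unchanged probe sets. On the real arrays none of the 158 probe sets that differed by at least 1 passed. For lists of 27 genes among 10630, camera reached unadjusted p below 0.05 in 50 of 50 draws shifted by -0.4 and in 2 of 50 unchanged draws. The simulated genes were drawn independently of each other, without differences between arrays that many genes share. The limma shares therefore do not give the share of real changes that would be called in these data. Nor do the camera counts show how camera behaves when the genes of a list are correlated. The simulated shift was also larger than the -0.24 found for the thalamus list below.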

Results

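Gene expression was measured in the ventral forebrain of E13.5 mouse embryos (the letter stands for embryonic day) that lacked the basic helix-loop-helix transcription factor Olig2 (Olig2-/-) and in Olig2+/+ embryos. The series design text calls the tissue ventral forebrain and the sample labels call it ventral telencephalon. Whether the dissected piece held thalamus or prethalamus, which lie in the diencephalon, is not given in the sources used here. Each array carried labelled RNA from a pool of 3 brains. The design text states 5 replicates per genotype, and 3 arrays per genotype were analysed here: knockout replicates 2, 4 and 5 and wild-type replicates 1, 4 and 5. Each array gave a log2 expression value for 45037 non-control probe sets, with array medians between 3.14 and 3.20 and 43.9% to 44.2% of the values above 4. P-values of limma, fry and the exact permutation tests below measure the spread between these 6 pooled arrays, whose number limits the precision of each value. Camera compares the genes of a list with other genes. At the preset correlation its p-values rest mainly on the spread between genes, not between arrays.

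Olig2, the targeted gene, was lower on all 3 knockout arrays than on any wild-type array. Its single probe set read 7.59 ± 0.15 in the knockout and 8.28 ± 0.12 in the wild type (log2, SD, n = 3 each), a 1.62-fold lower level. The log2 difference was -0.69 (SE 0.11, 95% interval -0.96 to -0.43), with limma's adjusted p = 0.511. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so the remaining signal need not come from functional transcript. Olig1, the neighbouring gene and close relative of Olig2, went the other way: its single probe set read 6.65 ± 0.46 in the wild type and 8.35 ± 0.29 in the knockout (log2, SD, n = 3 each). That is a 3.24-fold higher level, with a log2 difference of 1.69 (SE 0.27, 95% interval 1.04 to 2.35) and limma's adjusted p = 0.511. All knockout arrays lay above all wild-type arrays for Olig1, and neither gene passed the adjusted threshold of 0.05.

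**Figure D1:**
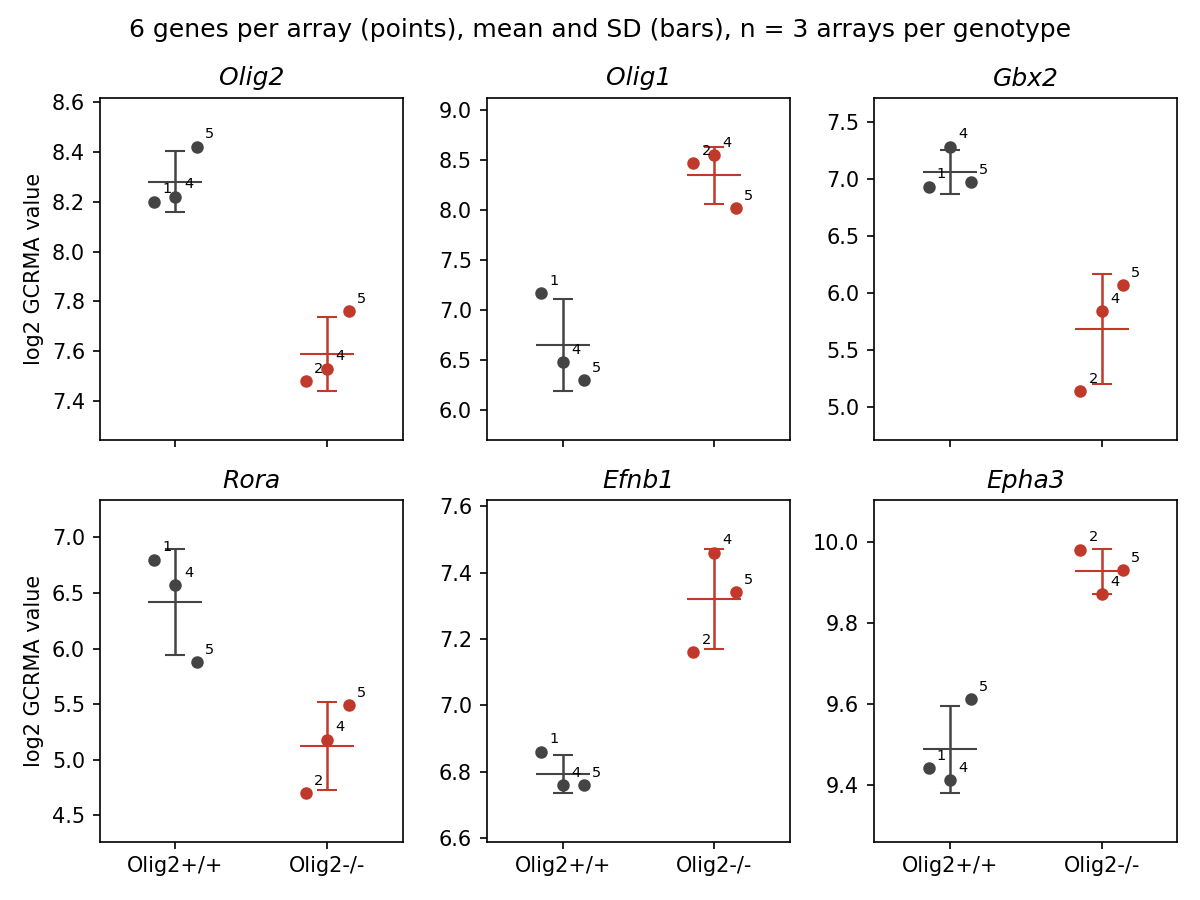
Log2 GCRMA values of 6 genes on each array, with 1 point per array (labelled with its replicate number) and bars for the mean and SD of the 3 arrays of a genotype; each panel has its own axis range. Olig2, Gbx2 and Rora were lower and Olig1, Efnb1 and Epha3 higher on every knockout array, and none of the 6 passed the adjusted threshold over all probe sets.

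The question of which transcripts differed between the genotypes was asked over 22565 probe sets that were above their array's median on at least 3 arrays. No probe set, and none of the 10630 genes they represent, passed adjusted p 0.05 in limma, and the smallest adjusted p was 0.511. At unadjusted p below 0.05 there were 2121 probe sets (9.4%), where 1128 are expected by chance, and 1124 of them were higher and 997 lower in the knockout. Splits of the 6 arrays that mix the genotypes gave from 319 to 1864 such probe sets. The 2 genotypes did not overlap for 3658 probe sets (16.2%, against 10% by chance). The count of 2121 was 1205 without knockout replicate 4, 1121 without knockout replicate 5, 1402 without wild-type replicate 1 and 3490 without wild-type replicate 4.

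Among the 10 genes of lowest p that were higher in the knockout, Notch2, a Notch receptor, was 0.71 higher on the log2 scale (8.90 ± 0.15 against 9.60 ± 0.19), and Lgr4, a receptor for R-spondins, was 0.76 higher (7.18 ± 0.14 against 7.94 ± 0.16). Gsk3b, a kinase of the Wnt pathway, was 0.86 higher at its brightest probe set, but other probe sets disagreed and the mean of all of them differed by -0.24. The others were Olig1, Sel1l3 (0.57), Prelid3a (0.54), Akirin1 (0.41), the mitochondrial protease Yme1l1 (0.69), Nipsnap2 (0.53) and Myef2 (0.36). A second probe set differed by 0.03 for Prelid3a and by -0.08 for Akirin1, and the other probe sets were 0.29 and 0.49 higher for Yme1l1 and 0.23 and 0.89 higher for Myef2. These 10 genes, and the 10 lower ones below, were ranked by p only among genes whose groups did not overlap, so the lack of overlap is no result. For all 20 limma's adjusted p was 0.511, so none passed.

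Among the 10 genes of lowest p that were lower in the knockout, Nkd1, an inhibitor of Wnt signalling, differed by -0.63 (5.72 ± 0.05 in the wild type, 5.10 ± 0.11 in the knockout) and the Wnt receptor Fzd1 by -0.45 (8.05 ± 0.06, 7.61 ± 0.06). Other kept probe sets differed by -0.40 and -0.12 for Nkd1 and by -0.01 for Fzd1. Chst1, a carbohydrate sulfotransferase, differed by -0.85, Lsm11, a part of the U7 snRNP, by -0.88, the kinase Map3k20 by -0.70, the receptor Tnfrsf19 by -0.61 and the microtubule-associated Map1a by -0.40. A second probe set gave -0.49 for Lsm11 and 0.02 for Map1a, and the probe sets of Tnfrsf19 ranged from -0.62 to -0.04. The remaining ones were Olig2, the predicted gene Gm6958 (-1.31) and the pseudogene Rps15a-ps6 (-0.72). Rps15a-ps6 had the lowest p of all 20 (6.84e-05 in limma, unadjusted), but it was dim (3.75 ± 0.04 in the wild type, 3.03 ± 0.08 in the knockout). Every knockout array read below its own median there, so the probe set was kept through the wild-type arrays alone. As a pseudogene it also resembles its parent gene, so its signal is uncertain.

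The series title names the prethalamus, and the list of prethalamic genes showed no common shift. Of 27 members measured, 9 were higher and 18 lower in the knockout, and none passed, over all genes or adjusted over the list alone. The mean was -0.07 relative to other genes (camera adjusted p = 0.761). It was -0.032 without wild-type replicate 1 (camera adjusted p = 0.816) and, in alternatives chosen after seeing the data, -0.112 without knockout replicate 2 and wild-type replicate 4 (0.481) and -0.046 with the cell cycle level as a covariate (0.84). Members of lowest p went in both directions. The homeobox gene Gsx2 was 0.54 higher (6.06 ± 0.12 in the wild type, 6.60 ± 0.19 in the knockout, SD, n = 3 each), Sp8 was 0.45 higher and Meis2 0.32 higher, while Zic5 differed by -0.52. The kept probe sets of Meis2 ranged from -0.13 to 0.32 and those of Zic5 from -0.72 to -0.05. Chosen after their values were seen, Dlx6os1 (0.40) and Six3 (-0.89) also had groups that did not overlap. Gsx2, Sp8, Meis2, Six3 and Isl1 also stand in the list of the lateral ganglionic eminence, and Dlx1 and Dlx2 in that of the medial ganglionic eminence. The sample labels call the tissue ventral telencephalon, so the mean of this list cannot tell prethalamus from ganglionic eminence.

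Genes of the thalamus and habenula were lower in the knockout as a group. Of 27 measured, 19 were lower and 8 higher, with a mean log2 difference of -0.25 and a mean of -0.24 relative to other genes. This was the only one of 35 lists past the threshold (camera with the preset correlation, p = 0.0011, adjusted p = 0.0385). With an estimated correlation the call was lost (p = 0.112, adjusted p = 0.953), and fry gave p = 0.0567. Gbx2, a homeobox gene of thalamic neurons, read 7.06 ± 0.19 in the wild type and 5.68 ± 0.48 in the knockout, a log2 difference of -1.38 (SE 0.25, 2.60-fold lower). It was the only member past the threshold adjusted over the list alone (adjusted p = 0.0481 from limma's p). Rora, an orphan nuclear receptor, differed by -1.29 (SE 0.30), Foxp2 by -0.56 (SE 0.16) and Barhl2 by -0.43 (SE 0.13), each with every knockout array below every wild-type array. Named after their values were seen, Tcf7l2 (-0.69), the netrin-G Ntng1 (-0.79) and Lhx9 (-0.52) were also lower, and Cdh6 was 0.55 higher. All 4 kept probe sets of Tcf7l2 were lower, from -0.94 to -0.49. The call for the list was lost without knockout replicate 2 (-0.16, adjusted p = 0.107 in camera), without knockout replicate 4 (-0.26, 0.0572) and without wild-type replicate 4 (-0.18, 0.22). With both knockout replicate 2 and wild-type replicate 4 left out, a choice made after seeing the data, the mean was -0.10 (camera adjusted p = 0.269). On knockout replicate 2 the thalamus list lay -0.27, the hypothalamus list -0.40 and the meninges and mesenchyme list 0.84 from the other knockout arrays. Between the genotypes the hypothalamus list differed by 0.05 and the meninges list by 0.17 relative to other genes.

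**Figure D2:**
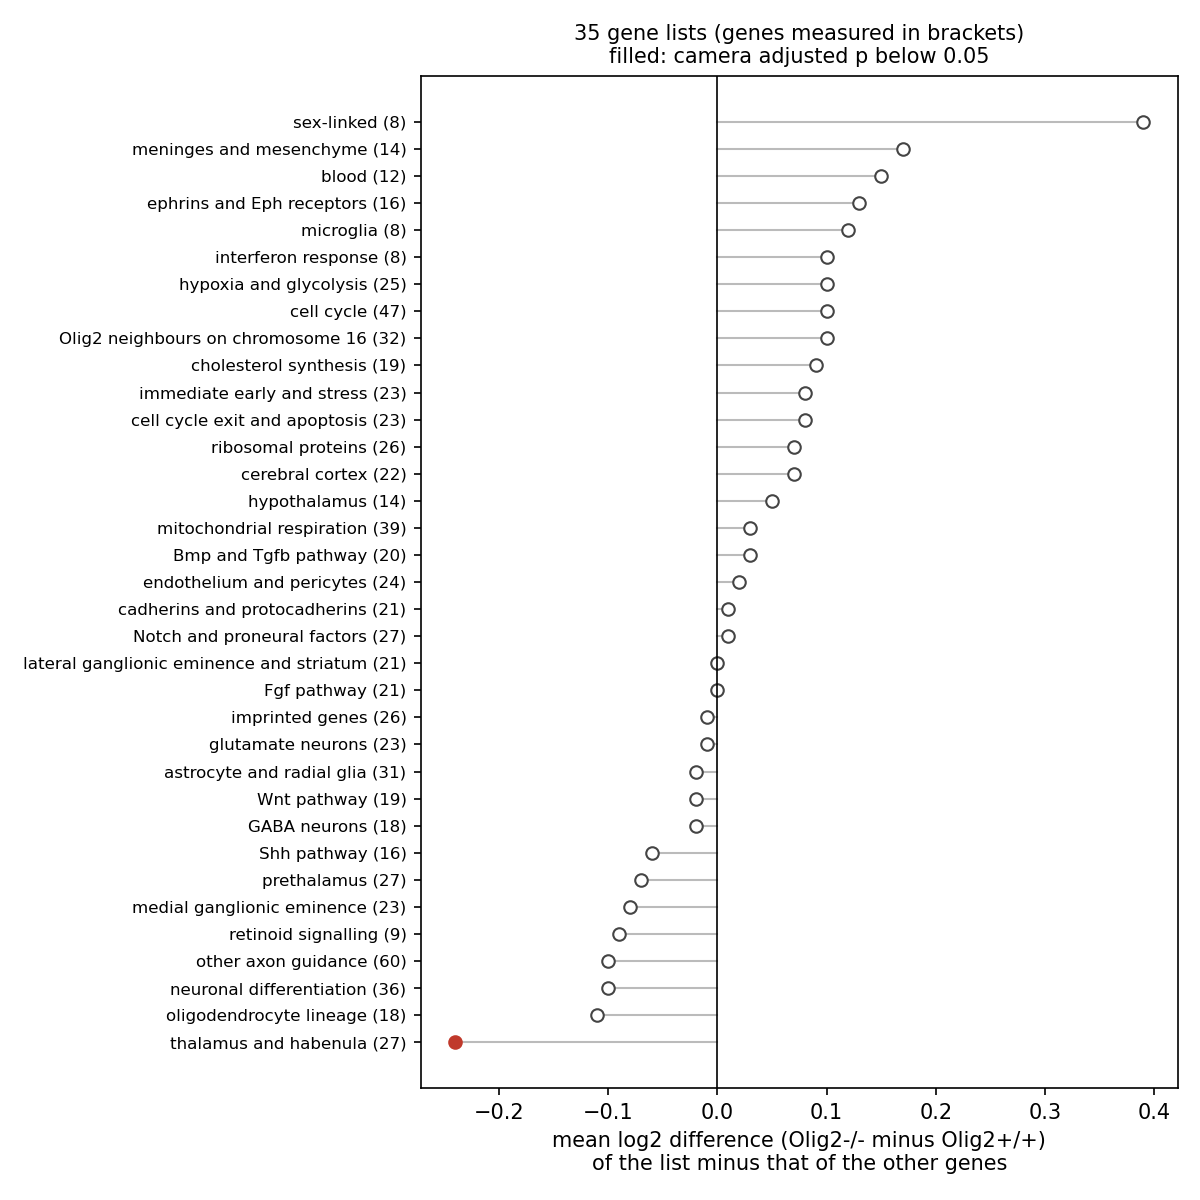
Mean log2 difference between knockout and wild type of each of 35 gene lists, minus that of all other genes measured (horizontal axis); the number in brackets is the count of genes measured, and the filled point is the list past camera's adjusted threshold. The thalamus and habenula list lies lowest at -0.24, and the sex-linked list lies highest at 0.39, where 1 wild-type array lacks Y-linked transcripts.

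Ephrins and Eph receptors, which guide axons by cell contact, were mostly higher in the knockout, short of the threshold over the lists. Of 16 measured, 13 were higher and 3 lower, with a mean of 0.13 relative to other genes (camera p = 0.00579, adjusted p = 0.101; p = 0.0416, adjusted p = 0.953, with an estimated correlation). Adjusted over the list alone, 2 passed, both higher: Efnb1 by 0.53 (6.79 ± 0.06 in the wild type, 7.32 ± 0.15 in the knockout) and Epha3 by 0.44 (9.49 ± 0.11, 9.93 ± 0.05), each with a limma-derived adjusted p of 0.0145. Efna1 was 0.29 higher and Efnb2 0.48 higher, without passing. The kept probe sets of Efnb1 ranged from 0.10 to 0.83, and the 4 of Epha3 all had the knockout arrays above the wild-type arrays, by 0.34 to 0.99. The list passed camera's threshold without knockout replicate 5 (0.156, adjusted p = 0.0222), without wild-type replicate 1 (0.145, 0.0446) and with repeated quantile normalization (0.137, 0.0447). It was farthest from the threshold without knockout replicate 2 (0.111, 0.294) among arrays left out singly, and had an adjusted p of 0.231 (0.115) with knockout replicate 2 and wild-type replicate 4 left out. Other axon guidance genes were mostly lower: 40 of 60, with a mean of -0.10 relative to other genes (camera adjusted p = 0.175; p = 0.414 with an estimated correlation). Without wild-type replicate 1 that mean was -0.032 (camera adjusted p = 0.778), and without wild-type replicate 5 the list passed (-0.137, 0.0222). No member passed over the list alone. The netrin receptor Unc5c differed by -0.34, Sema5b by -0.30 and Sema5a by -0.65, and a second probe set differed by 0.19 for Unc5c, by -0.72 for Sema5b and by -0.10 for Sema5a.

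The list of the oligodendrocyte lineage, which depends on Olig2 and Olig1 in the mouse central nervous system, held 18 measured genes, of which 14 were lower and 4 higher. Its mean was -0.11 relative to other genes (camera adjusted p = 0.102; p = 0.201 with an estimated correlation), and with no filter on dim probe sets, over 28 genes, it passed (camera adjusted p = 0.0282). Without wild-type replicate 1 the mean was -0.045 (camera adjusted p = 0.29). Olig1, a member of the list, was 1.69 higher over all arrays and 1.96 higher without wild-type replicate 1, which raises these means. The median log2 difference of the 18 genes was -0.16, against a mean of -0.12, both not taken relative to other genes. A list mean without Olig1 was not computed. Adjusted over the list alone, 3 passed: Olig1, higher, and the chondroitin sulfate proteoglycans Bcan and Ncan, both lower. Bcan read 5.02 ± 0.43 in the wild type and 4.06 ± 0.16 in the knockout (log2 difference -0.96, SE 0.23), and Ncan differed by -0.36 (SE 0.09), each with a limma-derived adjusted p of 0.0373 over the list alone. For Ncan the mean of its probe sets went the other way, at 0.13. The myelin genes Cnp (-0.32; other probe sets -0.14 and 0.07) and Mbp (-0.25) were lower without passing. Pdgfra, the receptor that marks oligodendrocyte precursors, differed by -1.04 (SE 0.49), and its groups overlapped.

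Genes of neuronal differentiation were mostly lower in the knockout and cell cycle genes mostly higher, neither past the threshold. Of 36 neuronal genes 28 were lower, with a mean of -0.10 relative to other genes (camera adjusted p = 0.102; p = 0.409 with an estimated correlation). The intermediate filament gene Ina differed by -0.60, Mapt by -0.56 and Syn1 by -0.60, while Syt4 was 0.42 higher. The other kept probe sets of Mapt ranged from -0.25 to 0.02. Of 47 cell cycle genes 32 were higher, with a mean of 0.10 (camera adjusted p = 0.175; p = 0.648 with an estimated correlation). Its member of lowest p, the replication gene Mcm4, was 0.40 higher, and 0.13 higher at a second probe set. On wild-type replicate 1 alone, the cell cycle list lay -0.32 and the neuronal list 0.24 from the other wild-type arrays. Without that array the cell cycle mean turned to -0.02 (camera adjusted p = 0.778) and the neuronal mean was -0.037 (0.601). Without wild-type replicate 5 both lists passed, at 0.19 for the cell cycle (camera adjusted p = 0.000317) and -0.157 for the neuronal list (0.00428), and the neuronal list also passed with repeated quantile normalization (-0.117, 0.0447).

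Other forebrain regions and signalling pathways showed single genes apart but no list past the threshold. Among cortical genes, Tbr1 was 0.45 higher (SE 0.11) and Neurod6 0.52 higher, and 14 of 22 cortical genes were higher (camera adjusted p = 0.495). The next members by p went the other way at their brightest kept probe sets, Lmo2 by -0.41 and Cux1 by -0.28. Of 23 genes of the medial ganglionic eminence, 17 were lower (camera adjusted p = 0.495), and the one past the threshold over the list alone was Gbx2, shared with the thalamus list. In the lateral ganglionic eminence and striatum, 9 of 21 were higher (camera adjusted p = 0.883). In the Wnt list, with 9 of 19 higher (camera adjusted p = 0.855), Nkd1 passed over the list alone (limma-derived adjusted p = 0.00575) and the secreted inhibitor Sfrp1 was 0.90 higher (SE 0.33). In the Notch list, with 13 of 27 higher (camera adjusted p = 0.88), Notch2 passed over the list alone (limma-derived adjusted p = 0.0465), the target gene Hes1 was 0.40 higher and Notch1 differed by -0.43. Of 16 genes of the Shh pathway, 10 were lower and 6 higher (camera adjusted p = 0.683), and groups did not overlap for 2 higher and 2 lower members. The receptor Ptch1 was among the lower genes (-0.26, and 0.18 at a dimmer probe set). Fry's test for change in either direction, which does not compare a list with other genes, passed its adjusted threshold for 7 lists. These were the Wnt (4.24e-07), Olig2 neighbour (0.0028), ephrin (0.0106), oligodendrocyte (0.0227), thalamus (0.0277), endothelium (0.0277) and lateral ganglionic eminence (0.0286) lists, with fry's adjusted p in brackets.

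Lists of other cells that a dissection can hold did not pass the threshold. The camera adjusted p was 0.495 for blood (9 of 12 higher) and microglia (6 of 8 higher), 0.855 for endothelium and pericytes, 0.88 for meninges and mesenchyme and 0.817 for the hypothalamus. Choroid plexus and midbrain and hindbrain lists had 4 genes measured each and the eye and pituitary list 2, too few for the test. The 32 measured neighbours of Olig2 on chromosome 16 had 18 higher and 14 lower (camera adjusted p = 0.495), and only Olig1 passed over the list alone. The 29 lists other than the thalamus, ephrin, oligodendrocyte, neuronal, axon guidance and cell cycle lists all had camera adjusted p of 0.495 or more.

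Of the RNA quality controls, the mean of the 18S ribosomal RNA probe sets was 5.55 ± 0.77 in the wild type and 6.48 ± 1.03 in the knockout, a log2 difference of 0.93 with overlapping groups (exact permutation p = 0.3, two-sided). The log2 difference between the 3' and 5' control probe sets of Actb was 0.77 ± 0.07 in the wild type and 0.82 ± 0.12 in the knockout (exact permutation p = 0.6, two-sided). For Gapdh it was -0.48 ± 0.06 and -0.61 ± 0.04 (exact permutation p = 0.1, the smallest that 3 arrays against 3 can give), with all knockout arrays lower. Hybridisation controls differed by -0.05 (exact permutation p = 0.6). On component 1 (42.6% of the variance) the knockout arrays lay between -27.05 and -3.24 and the wild-type arrays between 5.89 and 44.92, with wild-type replicate 1 farthest out. Component 2 (29.7%) set knockout replicate 2 and wild-type replicate 4 apart from the others. These 2 arrays of different genotype had the highest correlation across probe sets of any pair (Pearson r = 0.994), above the knockout pairs (0.981 to 0.992) and the wild-type pairs (0.978 to 0.987). Such a correlation across probe sets describes the arrays, since probe sets are not independent replicates. Wild-type replicate 1 lacked Y-linked transcripts: Eif2s3y read 3.04 there and 6.67 to 7.76 on the other arrays.

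**Figure D3:**
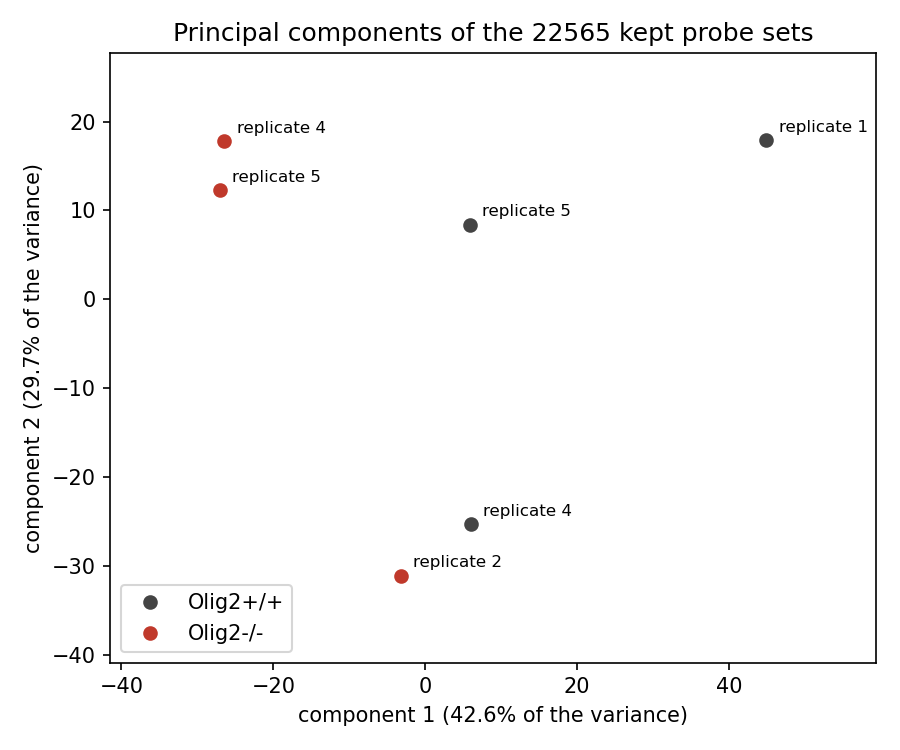
Position of each array on the first 2 principal components of the kept probe sets (axes in units of the component score, with the share of variance), with points coloured by genotype and labelled by replicate number. The knockout arrays lie to the left of the wild-type arrays, wild-type replicate 1 lies alone at the right, and knockout replicate 2 and wild-type replicate 4 lie together at the bottom.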

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

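The control probe sets printed on the array were not part of the comparison of genes, and in 5 of the 19 mouse controls the genotypes did not overlap: every knockout array lay above every wild-type array in 4 and below in 1. The choice to look at Tfrc probe sets outside the controls was made after these values were seen. The 3' probe set for 18S ribosomal RNA was 0.99 higher on the log2 scale in the knockout (5.57 ± 0.49 in the wild type, 6.56 ± 0.54 in the knockout, SD, n = 3 each). The 5' and middle 18S probe sets overlapped between the genotypes, with differences of 0.65 and 1.15, and the mean of all 3 differed by 0.93 (exact permutation p = 0.3). The 1 that was lower, the 3' probe set for Actb, differed by -0.27 (14.4 ± 0.09, 14.13 ± 0.17). The 5' probe set for Gapdh was 0.12 higher, and its 3' probe set differed by -0.01. For the transferrin receptor, the 3' control was 0.83 higher (4.91 ± 0.38, 5.73 ± 0.30) and the middle one 0.23 higher (3.52 ± 0.14, 3.75 ± 0.06). The regular Tfrc probe sets differed by 1.02, 1.02 and 0.18, the last at the brightest of them (8.74 ± 0.14, 8.92 ± 0.19). With 3 arrays per genotype, 10% of probe sets separate this way, in either direction, by chance, and 16.2% of the kept probe sets did so in these data. Several of the 19 controls measure the same transcript, so they are not independent.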

How the results depend on the processing

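No probe set and no gene passed adjusted p 0.05 in limma under any setting run, and the fold limit left 0 as well. The 83 genes followed gave 1409 values under the alternatives, of which 1406 kept their direction and 0 passed, with a smallest adjusted p of 0.137. Olig2 and Olig1 kept their direction throughout, with limma's adjusted p between 0.204 and 0.838 for Olig2 and between 0.222 and 0.838 for Olig1. Averaging the probe sets of a gene turned Gsk3b to -0.24, Ncan to 0.13 and Cryzl1 to -0.02, since their probe sets disagree. The pair block, the pair left out and the cell cycle covariate were chosen after seeing the data. The number of probe sets at unadjusted p below 0.05, 2121, was 3491 with array weights, 3276 with knockout replicate 2 and wild-type replicate 4 left out, and 1121 to 3490 with 1 array left out. The number of lists past the threshold, 1 in camera, was 2 with no filter, 3 with repeated quantile normalization, 0 with the log2 above 4 filter, 0 with array weights, 0 with an estimated correlation, 0 in fry, 0 with the pair block, 0 with the pair left out, and 0 to 4 with 1 array left out. The thalamus list stayed lower under all settings run but missed the threshold with the log2 above 4 filter (-0.242, camera adjusted p = 0.057), array weights (-0.19, 0.071), an estimated correlation (-0.236, 0.953), the pair block (-0.236, 0.053) and the pair left out (-0.102). It also missed the threshold in fry (adjusted p = 0.745), which tests the list against no change and not against other genes. With 1 array left out its mean ranged from -0.282 to -0.163. The cause of these changes was not tested, beyond the fewer arrays where some were left out. The cell cycle list turned to -0.016 with array weights and -0.023 without wild-type replicate 1, where the range with 1 array left out reached 0.19. With the replicate number as a block, which only numbers 4 and 5 can inform, 2014 probe sets were at unadjusted p below 0.05, 0 passed, the thalamus list stood at -0.194 (camera adjusted p = 0.0257), the prethalamus list at -0.043 (0.605), the ephrin list at 0.121 (0.462) and the cell cycle list turned to -0.033. Deviations from the genotype mean correlated at -0.29 across probe sets for the arrays numbered 4 and at 0.32 for those numbered 5, so the numbers were not taken to pair the arrays. The 3 against 3 arrays have 10 splits, too few for a share under 0.05. The real split gave 2121 probe sets at unadjusted p below 0.05, as 1 of the 10 splits did, and the highest other gave 1864. At adjusted p 0.05 the real split gave 0 probe sets, and 2 splits that mix the genotypes gave 1 each. For lists past camera's threshold the real split gave 1, as many or more came from 8 of the 10 splits, and the highest other gave 9. About 33% of values lie at the floor of the scale, where no difference can be measured.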

Other observations

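In the observations below, the tests of RNA degradation, embryo age, Y-linked transcripts, genotype labels and 18S RNA were chosen after the result was seen. So were those that left out a pair of arrays, the cell cycle covariate and the count of splits by adjusted p. Leaving out wild-type replicate 1 was an alternative fixed beforehand, but its use as a test of the thalamus list was chosen afterwards.

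Levels of some genes set arrays apart within a genotype. Ttr, the transthyretin gene that is abundant in choroid plexus, read 9.99 on knockout replicate 2 and 10.96 on wild-type replicate 4, against 6.42 and 4.85 on the other knockout arrays and 8.36 and 3.46 on the other wild-type arrays. The embryonic globin Hbb-bh1 read 8.19, 7.95 and 8.14 on knockout replicate 2 and wild-type replicates 1 and 4, and 9.05 to 9.48 on the other 3 arrays. On knockout replicate 2 the meninges and mesenchyme list lay 0.84 above the other knockout arrays, the hypothalamus list at -0.40 and the thalamus list at -0.27 from them. The 2 measured genes of the eye and pituitary list averaged -0.54 there from their mean over all arrays, against 0.40 and 0.21 on the other knockout arrays. On knockout replicate 4 the hypoxia and glycolysis list lay 0.35 above the other knockout arrays. On wild-type replicate 5 the cell cycle list lay 0.27 above the other wild-type arrays. These are values of single arrays, given without a test.

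Probe sets of one gene also differed. For Actb, one probe set was 1.35 higher in the knockout (7.87 ± 0.15 in the wild type, 9.21 ± 0.25 in the knockout) while a brighter one differed by -0.22 (13.94 ± 0.04, 13.72 ± 0.21). Dyrk1a, a neighbour of Olig2 on chromosome 16, was 1.36 higher at its dimmest kept probe set and 0.29 and 0.30 higher at the others. Ifnar1, another neighbour, differed by -1.46 at one probe set (6.45 ± 0.16, 4.99 ± 0.93) and by 0.07 at a brighter one.

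Wild-type replicate 1 lay at 44.92 on component 1, where the other wild-type arrays lay at 5.97 and 5.89, and its cell cycle list was at -0.32 from them. Older embryos stay open: embryonic minus adult alpha globin (its brightest probe set, since the single-symbol ones were near the floor) was -2.37 there, below the other wild-type arrays (-2.32 and -1.47) but not below knockout replicate 2 (-2.43). Its embryonic globin mean (10.39) and Hbb-bh1 (7.95) were the lowest of the 6 arrays, and Hbb-y was between 13.94 and 14.11 on all arrays, near the top of the scale. Adult alpha globin (12.76) and the blood list (-0.25 from its mean over all arrays) were also lowest there, so the low embryonic globins alone do not point to age. Degraded RNA stays open but is not shown: the Gapdh 3' minus 5' difference was -0.41, above the others (-0.65 to -0.50). It was still negative, so the 5' signal was the brighter one there too, and the difference of Actb (0.80) lay inside the range of the other arrays. A pool without male embryos cannot be told apart from the array itself, because Eif2s3y was at background (3.04) on this array alone.

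Knockout replicate 2 and wild-type replicate 4 resembled each other more than either resembled its own genotype. A wrong genotype label is argued against by all 4 Olig2 and Olig1 values of the 2 arrays, which lay beyond every array of the other genotype. More nuclear RNA stays undecided. A set of 8 nuclear-retained RNAs differed from the other arrays of the genotype by a mean of -0.23 (SE 0.12 over genes), from -0.74 for Rian to 0.25 for Sox2ot. That SE treats the genes as independent, and Malat1, left out of the set, was 1.37 higher. A shared preparation with more ribosomal RNA stays open: the 18S mean was above both other arrays of the genotype on 2 of the 2 arrays. Its value on wild-type replicate 4 (6.39) was, however, close to that on knockout replicate 4 (6.34). The 4 measured choroid plexus genes averaged 0.69 and 0.72 on these 2 arrays from their mean over all arrays, against -0.95 to 0.16 on the others. A shared litter or dissection was not tested.

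The lower thalamus list is a hypothesis of a genotype effect with open technical alternatives, and a difference in how much diencephalon was dissected stays open: the hypothalamus list, which shares Dbx1 and Lhx9 with the thalamus list, was also lower on knockout replicate 2 (-0.40) but differed by 0.05 between the genotypes. Wild-type replicate 1 as its only source is argued against, since the mean was -0.267 without it (camera adjusted p = 0.000552). With the cell cycle level as a covariate the mean was -0.245 (camera adjusted p = 0.00839), so the shift did not follow that level. A more advanced stage of the wild-type arrays stays open, because whether the cell cycle level tracks stage was not tested. That level varied mainly between wild-type replicates 1 (-0.26 from the mean of all arrays) and 5 (0.14), whose thalamus lists lay at 0.09 and 0.07. Both values are with camera's preset correlation, and over all arrays the call for the thalamus list was lost with an estimated correlation (p = 0.112, adjusted p = 0.953). Much of its size may come from knockout replicate 2 and wild-type replicate 4: without both the mean was -0.102 (camera adjusted p = 0.269), and it was -0.51 between these 2 arrays (22 of 27 genes lower) against -0.10 between the other 4 (17 of 27 lower). Gbx2 differed by -2.14 between the 2 arrays and by -1.0 between the other 4, and Rora by -1.87 and -1.0. Of 10 splits, too few for a share under 0.05, 1 gave a mean as large as the real size of 0.236 and the highest other gave 0.181; by camera adjusted p, 3 of the 10 splits were as small as the real 0.0385, the others at 0.0284 and 0.00805.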
